A study of Mus musculus with 12 samples.

How the data were processed

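The data are RNA-seq profiles of 12 libraries of colonic stromal cells, 4 each from normal adult colon, colon at postnatal day 14 (2 weeks) and AOM/DSS tumours, all from C57BL/6J mice. Per the labels' protocols, colon pieces were digested with collagenase IV and dispase, and DAPI-negative cells negative for EPCAM, CD31, CD45 and TER119 were sorted. Polyadenylated RNA was made into stranded libraries and read as single ends of 75 bases. The authors deposited 1 table of raw counts per gene, not normalized, with 1 column per library. Per the submitters' processing notes, STAR 2.4.2a, edgeR 3.28.0 and the build GRCm38 were used, without a statement of what each did. The counting tool, the annotation, the strand setting and the handling of reads with several matches are not given in the sources used here. Reads of overlapping or antisense genes and of near-identical gene copies may therefore be assigned to either, and values of such genes are uncertain.

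The table lists 19049 genes, each with at least 12 counts in total, so genes with few or no counts were left out before deposit. Of the listed genes, 2037 have a count of 0 in some library. Counts come from reads without molecular identifiers, so counting intervals and floors cover counting error only. Gene IDs matched GENCODE M21 on GRCm38 for 19012 genes and not for 37. Every column mapped to 1 sample by its title. Within groups, pairs of libraries differed by a chi-square per degree of freedom of 11.7 to 238, so no library was a copy of another. The labels name separate mice in each group. The title numbers are shared between groups, but only 3 of 6 same-number pairs had a correlation of deviations over 0.1, so they were treated as names only.

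All tests were run in R 4.3.3 on the counts as deposited. The main test was the quasi-likelihood F test of edgeR 4.0.16 with TMM factors, fitted to all 12 libraries so that the groups share 1 estimate of the spread. Genes passed filterByExpr with its minimum count of 10 and minimum total count of 15, which kept 18727 genes and removed 322. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The common biological coefficient of variation was 0.333 and the prior degrees of freedom were 3.61. Log2 fold changes carry the SE from the fitted model, and CPM values, marker sums included, are counts scaled to the library totals times the TMM factors, with the SD over 4 libraries, except for Xist, which is scaled to the totals alone. The comparisons were P14 against normal adult, tumour against normal adult, and tumour against P14. Sex is not given per library and age is fixed by group, so neither was a term of the main model.

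Lists of genes were written down for cell types, matrix, growth signals, immunity, metabolism and technical responses, 53 in all, and tested with camera of limma 3.58.1 at a preset correlation between genes of 0.01, adjusted over the lists of 1 comparison. Camera called 29, 16 and 20 lists in the 3 comparisons. With the correlation estimated from the data, 2, 0 and 0 were called, with 6, 6 and 6 at an unadjusted p under 0.05; the 2 were matricellular proteins and imprinted growth genes at P14. The rotation test fry, which asks whether the genes of a list move one way on balance, called 35, 23 and 28. Marker sums of 20 cell types were compared by an exact two-sided permutation test over 70 assignments of 8 libraries. The 53 lists, these tests and the rule for named genes were fixed before the data were examined. Named genes were the 10 study genes, the 8 largest rises and 8 largest falls per comparison among called genes with a mean of at least 5 CPM, no overlap between groups and no predicted, immunoglobulin, T cell receptor or sex-linked gene, up to 4 members per described list, and the 8 largest shared rises and falls. Some list members that this rule had picked are not reported here. Of the 4 members per list, the text prints 1 to 3, mostly those whose call no single left-out library ended.

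The gene, list and overlap steps were tested on simulated counts with known changes. At P14 against normal adult, the gene test recovered 89.4% of 4-fold, 25.4% of 2-fold and 1.49% of 1.5-fold changes among 18631 genes, with 6 false calls of 83. For tumour against normal adult the shares were 84.8%, 37.3% and 4.48% among 18643 genes with 5 false calls of 89, and for tumour against P14 they were 83.3%, 35.8% and 2.99% among 18635 genes with 7 of 88. Camera recovered 5 of 5 lists raised 2-fold in each comparison, with 2, 0 and 0 false calls. The overlap step recovered 88 of 100 genes changed 4-fold in the same direction and 89 of 100 in opposite directions among 18619 genes. Changes of 1.5-fold are thus mostly missed here. Alternatives to normalization, filter, test, threshold, samples and covariates were run, including DESeq2 1.42.0, limma voom and a surrogate variable from sva 3.50.0.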

Results

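Stromal cells of the mouse colon were profiled by RNA-seq in 3 groups of 4 C57BL/6J mice: normal adult colon at 8 weeks, colon at postnatal day 14 (P14), and colonic tumours at 12 to 14 weeks. The tumours were raised with azoxymethane (AOM), a carcinogen, and dextran sodium sulfate (DSS), which injures the colonic lining. The cells were sorted as live cells that lacked EPCAM, CD31, CD45 and TER119, which mark epithelial, endothelial, blood-derived and red-lineage cells. Total counts ranged from 26392364 to 29911817 in normal adult libraries, from 29499836 to 38799033 in P14 libraries and from 15449444 to 28471598 in tumour libraries. Tumour replicate 4 had the lowest total and 9.14% of listed genes at 0, against 1.40% or less in the other 11 libraries. The first principal component of the 500 most variable genes held 52.2% of the variance and parted the tumour libraries from the others, and the second held 24.1% and parted normal adult from P14 libraries. The design states 2 males and 2 females per group. Normal adult replicates 1 and 2 and P14 replicates 2 and 3 had Xist under 1 CPM together with Y-linked counts, whereas all 4 tumour libraries had Xist at 481 to 1395 CPM with at most 1 count over 4 Y-linked genes. Values after ± are SEs for log2 fold changes and SDs for CPM, with n = 4 libraries per group throughout.

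**Figure D1:**
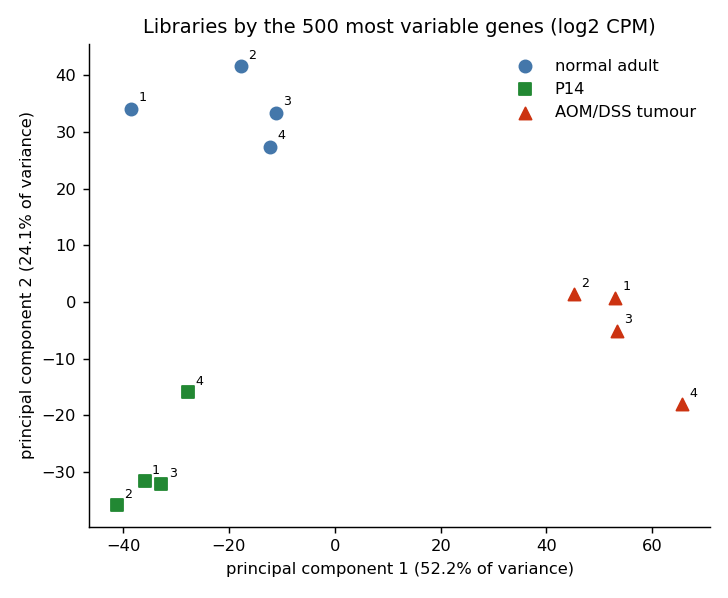
Each point is 1 of the 12 libraries, placed by its scores on the first (x axis, 52.2% of variance) and second (y axis, 24.1%) principal components of log2 CPM of the 500 most variable genes. The 4 tumour libraries lie between 45.2 and 65.6 on the first component and the other 8 libraries lie below 0.

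The first comparison set the growing colon at P14 against the adult colon, which the design text calls prenatal although the samples are postnatal. By camera, lists of contractile, pericyte and extracellular matrix genes were higher at P14, and those of epithelial, leukocyte and antigen-presentation genes lower. With estimated correlation only 2 of the 29 lists called, matricellular proteins and imprinted growth genes, were called. Mcam, an adhesion molecule of pericytes, smooth muscle and endothelium (ENSMUSG00000032135, chromosome 9, 44134469 to 44142727 on the plus strand, GRCm38), rose from 65.3 ± 16.1 to 284 ± 37.6 CPM (fold 4.34, log2 fold change 2.12 ± 0.18, adjusted p = 5.9e-05). Acta2, the smooth muscle actin of contractile cells, rose from 389 ± 92.8 to 1702 ± 490.5 CPM (log2 fold change 2.13 ± 0.26, adjusted p = 0.000275), and Lox, the enzyme that crosslinks collagen and elastin, rose from 60.4 ± 10.8 to 491 ± 52.4 CPM (log2 fold change 3.02 ± 0.22, adjusted p = 4.84e-05). Slc26a3, the chloride and bicarbonate exchanger of absorptive colonocytes, fell from 233 ± 102 to 5.01 ± 4.06 CPM (log2 fold change -5.53 ± 0.82, adjusted p = 0.00073, and -6.20 without P14 replicate 4). Of 18727 tested genes, edgeR's quasi-likelihood test called 5789 at an adjusted p under 0.05, 2797 higher and 2992 lower in P14. Of all tested genes, the values of 8112 (43.32%) did not overlap between the groups, against 2.86% by chance.

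Of the 10 genes picked in advance from the study's subject, 3 rose at P14, 7 did not pass, and 3 rose when adjusted over the list alone. This list (adjusted p = 0.0129 by camera and adjusted p = 0.378 with estimated correlation) was chosen from what the study is about and is no independent evidence of direction. Postn, a matricellular protein, was the third to rise, from 3573 ± 789.9 to 10159.7 ± 1969 CPM (log2 fold change 1.51 ± 0.38, adjusted p = 0.00967). Pdgfra, the receptor of most colonic fibroblasts, stood at 1014 ± 156 CPM in normal adult and 917 ± 65.3 CPM in P14 libraries (log2 fold change -0.14 ± 0.26, adjusted p = 0.714). The changes of the others were 0.57 ± 0.47 for Fap, 0.36 ± 0.25 for Pdgfrb, 0.36 ± 0.25 for Gli1 and 0.18 ± 0.29 for Islr, and -0.18 ± 0.33 for Grem1 and -0.38 ± 0.35 for Lepr, with adjusted p from 0.295 to 0.712.

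**Figure D2:**
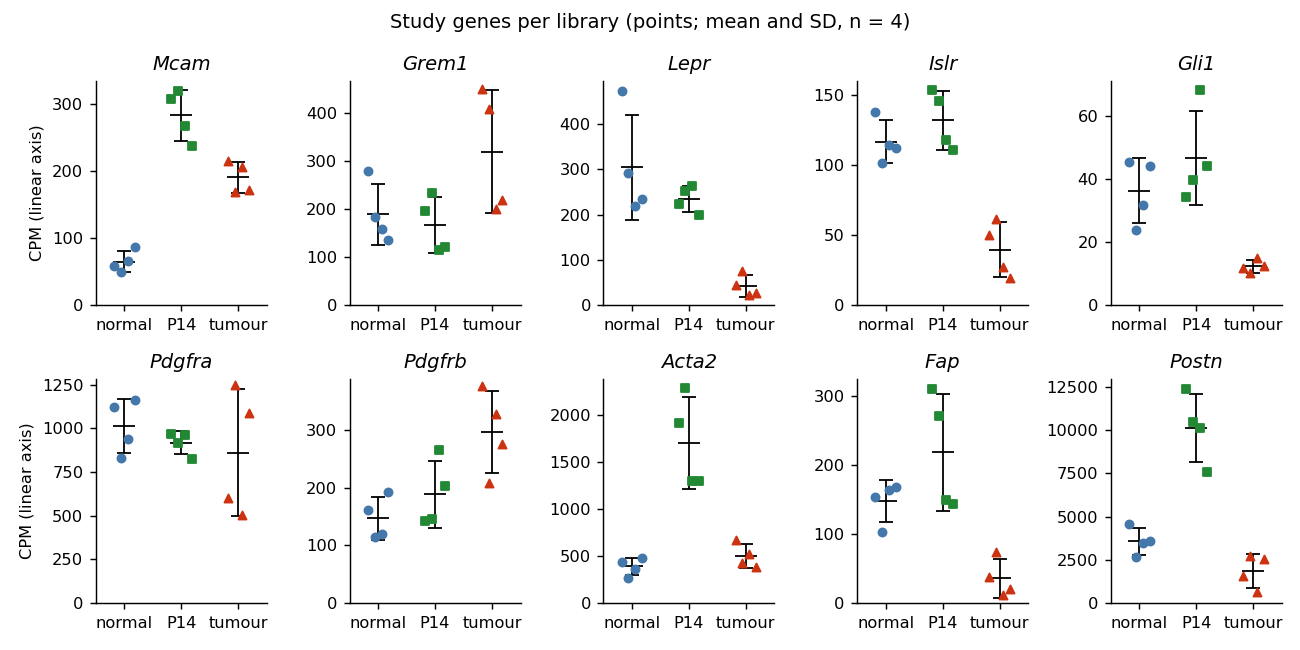
CPM (y axis, linear) of study genes in each library (points) by group (x axis), with the mean and SD of the 4 libraries. Mcam stands at 65.3, 284 and 191 CPM in normal adult, P14 and tumour libraries, while Lepr, Islr and Gli1 are lowest in the tumour libraries.

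The 8 largest rises at P14 were picked by a fixed rule on size and level. H19, an imprinted noncoding RNA (ENSMUSG00000000031, chromosome 7, 142575529 to 142578143 on the minus strand), rose from 2.56 ± 1.21 to 112 ± 92.7 CPM, a log2 fold change of 5.46 ± 0.87 (adjusted p = 0.00103). Sox11, a transcription factor of embryonic tissues, rose by 4.97 ± 0.50, and Mdk, the growth factor midkine, by 4.57 ± 0.36 on the log2 scale. The other rises were 5.14 ± 0.72 for Col26a1, 4.86 ± 0.39 for Cpz, 4.41 ± 0.84 for Nrk, 4.28 ± 0.55 for Cthrc1 and 4.03 ± 0.61 for Serpina3f, with adjusted p from 5.25e-05 to 0.00248 over these 7 genes. Of the 8 largest falls, Jchain, which links immunoglobulin polymers of plasma cells, changed by -6.51 ± 1.45. Slc26a3, Fabp2, the intestinal fatty acid binding protein, and the carbonic anhydrase Car4 belong to absorptive epithelium (-5.12 ± 0.90 for Fabp2 and -5.33 ± 0.83 for Car4). The rest were -5.77 ± 0.64 for Ceacam10, -5.61 ± 0.91 for Inmt, -5.37 ± 0.61 for Ces1f and -5.18 ± 0.66 for Ces2a, with adjusted p from 0.000157 to 0.00526 over the 8. Without P14 replicate 4, which had the highest epithelial marker sum of its group, the changes were -6.20 for Slc26a3, -5.73 for Fabp2, -6.38 for Car4 and -5.99 for Ces2a. That of Jchain was -8.11 without P14 replicate 3, and that of Inmt was -5.02 without normal adult replicate 1. Ces1f, Ces2a and Serpina3f have close copies in the genome, so these values are uncertain.

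Contractile, pericyte and neuron lists were higher at P14 by camera. Of 15 smooth muscle contractile genes, 14 rose and 1 did not pass, and 15 rose when adjusted over the list alone. Camera on smooth muscle contractile genes gave adjusted p = 1.12e-13, or 0.281 with estimated correlation. Log2 fold changes were 3.05 ± 0.39 for Actg2, 2.90 ± 0.34 for Cnn1 and 2.69 ± 0.37 for Des (adjusted p from 0.000241 to 0.00047). Of 10 pericyte markers, 8 rose and 2 did not pass, and 9 rose when adjusted over the list alone. Camera on pericyte markers gave adjusted p = 2.24e-06, or 0.369 with estimated correlation. Among them Rgs5, a regulator of G protein signals in pericytes, rose from 357 ± 84.7 to 1145 ± 237 CPM, with a log2 fold change of 1.68 ± 0.27, and Kcnj8, a potassium channel of pericytes, changed by 1.75 ± 0.24 (adjusted p from 0.000535 to 0.00108). The summed CPM of the smooth muscle list was 2182 ± 493 in normal adult and 8027 ± 2508 in P14 libraries, and that of the pericyte list was 769.9 ± 192 and 1995 ± 392. Of 11 enteric neuron markers, 8 rose and 3 did not pass, and 8 rose and 1 fell when adjusted over the list alone. Camera on enteric neuron markers gave adjusted p = 0.000362, or 0.369 with estimated correlation. Nos1, which makes nitric oxide in inhibitory neurons, rose from 0.491 ± 0.192 to 4.27 ± 2.22 CPM and Syt1, a synaptic vesicle protein, from 0.297 ± 0.0495 to 2.33 ± 0.831 CPM (adjusted p from 0.00157 to 0.00208), all low levels. Each of these 3 sums was higher in every P14 library than in every normal adult library, with an exact two-sided permutation p = 0.0286, the smallest that 70 assignments allow, and adjusted p = 0.0476 over 20 lists.

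Matrix lists were higher by camera as well. Of 16 interstitial collagens, 12 rose and 4 did not pass, and 12 rose when adjusted over the list alone. Camera on interstitial collagens gave adjusted p = 2.08e-07, or 0.281 with estimated correlation. Col1a2 rose from 3765 ± 233 to 13852 ± 833 CPM and Col1a1 from 1162 ± 267 to 4346 ± 1593 CPM, with log2 fold changes of 1.88 ± 0.20 and 1.90 ± 0.34 (adjusted p from 0.000135 to 0.00185). Of 19 genes of collagen processing and crosslinking, 14 rose, 1 fell and 4 did not pass, and 16 rose and 1 fell when adjusted over the list alone. Camera on collagen processing and crosslinking gave adjusted p = 2.23e-07, or 0.369 with estimated correlation. The prolyl hydroxylase P4ha2 changed by 1.47 ± 0.21 and the collagen chaperone Fkbp10 by 1.49 ± 0.19, while Pcolce2, an enhancer of procollagen cleavage, changed by -3.00 ± 0.56 (adjusted p from 0.000312 to 0.0022). Of 15 elastic fibre genes, 9 rose, 2 fell and 4 did not pass, and 9 rose and 2 fell when adjusted over the list alone. Camera on elastic fibre gave adjusted p = 0.0011, or 0.378 with estimated correlation. Fbn2, the fibrillin of growing tissue, rose from 33.3 ± 5.59 to 348 ± 75.5 CPM, and the microfibril gene Mfap2 changed by 2.48 ± 0.23 (adjusted p from 8.04e-05 to 0.000135). Of 18 basement membrane genes, 11 rose and 7 did not pass, and 13 rose when adjusted over the list alone. Camera on basement membrane gave adjusted p = 1.63e-05, or 0.369 with estimated correlation. Col4a1 rose from 1722 ± 362 to 4411 ± 1081 CPM and Nid2 from 19.9 ± 3.66 to 76.5 ± 12.6 CPM (adjusted p from 6.48e-05 to 0.000951). Of 12 matricellular proteins, 7 rose and 5 did not pass, and 8 rose when adjusted over the list alone. Camera on matricellular proteins gave adjusted p = 2.15e-06, or 0.0234 with estimated correlation. Sparc rose from 1478 ± 117 to 4507 ± 503 CPM and Ccn4 from 12.8 ± 1.44 to 42.1 ± 4.83 CPM (adjusted p from 0.000133 to 0.000146). Of 20 matrix proteases and inhibitors, 7 rose, 2 fell and 11 did not pass, and 8 rose and 2 fell when adjusted over the list alone. Camera on matrix proteases and inhibitors gave adjusted p = 0.0169, or 0.407 with estimated correlation. Adam12 changed by 2.52 ± 0.20 and Adamts12 by 1.38 ± 0.15 (adjusted p from 5.25e-05 to 0.000157). Of 14 cancer-associated fibroblast markers, 5 rose and 9 did not pass, and 5 rose when adjusted over the list alone. Camera on cancer-associated fibroblast markers gave adjusted p = 0.00174, or 0.369 with estimated correlation. The members that rose were matrix and contractile genes already named or Lrrc15 (log2 fold change 3.13 ± 0.64, adjusted p = 0.00345).

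Growth and signalling lists were higher by camera. Of 15 imprinted growth genes, 12 rose and 3 did not pass, and 13 rose when adjusted over the list alone. Camera on imprinted growth genes gave adjusted p = 6.94e-08, or 0.0494 with estimated correlation. Mest rose from 5.12 ± 1.09 to 31.7 ± 10.8 CPM and Nnat from 5.06 ± 0.457 to 19.3 ± 1.76 CPM (adjusted p from 0.000649 to 0.000653). Of 26 proliferation genes, 10 rose, 1 fell and 15 did not pass, and 20 rose and 1 fell when adjusted over the list alone. Camera on proliferation gave adjusted p = 1.39e-06, or 0.407 with estimated correlation. Rrm2, a subunit of ribonucleotide reductase, and the spindle factor Tpx2 changed by 2.06 ± 0.31 and 1.49 ± 0.29 (adjusted p from 0.000785 to 0.00286), whereas Plk1, a mitotic kinase, changed by -1.58 ± 0.39 (adjusted p = 0.00878). Of 8 WNT inhibitors, 4 rose and 4 did not pass, and 5 rose and 1 fell when adjusted over the list alone. Camera on WNT inhibitors gave adjusted p = 0.0231, or 0.369 with estimated correlation. Dkk2 rose from 9.52 ± 2.51 to 50.1 ± 16.5 CPM and Frzb from 4.21 ± 1.55 to 14.5 ± 3.32 CPM (adjusted p from 0.00072 to 0.0016). Of 12 Hedgehog pathway genes, 4 rose and 8 did not pass, and 4 rose when adjusted over the list alone. Camera on Hedgehog pathway gave adjusted p = 0.0143, or 0.407 with estimated correlation. The gut mesenchyme factor Foxf1 changed by 1.18 ± 0.19 and the receptor Smo by 0.98 ± 0.20 (adjusted p from 0.00113 to 0.00306). Of 13 TGF-beta ligands and targets, 5 rose and 8 did not pass, and 5 rose when adjusted over the list alone. Camera on TGF-beta ligands and targets gave adjusted p = 0.0129, or 0.378 with estimated correlation. Tgfbi and Tgfb2 changed by 1.20 ± 0.24 and 0.93 ± 0.18 (adjusted p from 0.00244 to 0.00288). Of 10 BMP antagonists, 5 rose and 5 did not pass, and 5 rose when adjusted over the list alone. Camera on BMP antagonists gave adjusted p = 0.0231, or 0.407 with estimated correlation. Chrdl1 changed by 1.30 ± 0.32 (adjusted p = 0.00982). Of 16 immediate early and dissociation genes, 9 rose and 7 did not pass, and 10 rose when adjusted over the list alone. Camera on immediate early and dissociation genes gave adjusted p = 0.00869, or 0.407 with estimated correlation. Nr4a1 rose from 153 ± 16.1 to 385 ± 113 CPM and Fos from 1207 ± 196 to 2009 ± 46.9 CPM (adjusted p from 0.00211 to 0.00893). These genes respond within minutes to tissue digestion as well as to signals in the tissue.

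Epithelial, macrophage, B cell, erythroid and MHC lists were lower at P14 by camera. Of 18 epithelial markers, 18 fell, and 18 fell when adjusted over the list alone. Camera on epithelial markers gave adjusted p = 5.18e-12, or 0.369 with estimated correlation. Their summed CPM was 11050.0 ± 4168 in normal adult and 1271 ± 1209 in P14 libraries, with 3073 CPM in P14 replicate 4 and 470.4 to 776.1 CPM in the others. Car1, a carbonic anhydrase of surface colonocytes, changed by -4.63 ± 0.98 and Phgr1 by -4.03 ± 0.58 (adjusted p from 0.000633 to 0.00409), and by -5.56 and -4.83 without P14 replicate 4. Of 13 macrophage and pan-leukocyte markers, 11 fell and 2 did not pass, and 1 rose and 11 fell when adjusted over the list alone. Camera on macrophage and pan-leukocyte markers gave adjusted p = 5.73e-06, or 0.369 with estimated correlation. The complement C1q genes of macrophages changed by -3.23 ± 0.61 for C1qa, -3.00 ± 0.63 for C1qb and -2.94 ± 0.67 for C1qc (adjusted p from 0.00236 to 0.00612), and the sum of this list was 213 ± 28.9 and 39.5 ± 8.14 CPM. Of 7 B and plasma cell markers, 4 fell and 3 did not pass, and 5 fell when adjusted over the list alone. Camera on B and plasma cell markers gave adjusted p = 0.0187, or 0.407 with estimated correlation. Their sum was 736 ± 559 and 13.4 ± 14.0 CPM, with 34.11 CPM in P14 replicate 3 and 3.375 to 9.209 CPM in the other P14 libraries, led by Igha, the heavy chain of immunoglobulin A (log2 fold change -6.40 ± 1.47, adjusted p = 0.00636, and -7.99 without P14 replicate 3). Of 5 erythroid markers, 5 fell, and 5 fell when adjusted over the list alone. Camera on erythroid markers gave adjusted p = 0.00601, or 0.378 with estimated correlation. Hba-a1 changed by -2.72 ± 0.63, at low levels and with reads shared between globin copies. Of 7 genes of MHC class II presentation, 6 fell and 1 did not pass, and 7 fell when adjusted over the list alone. Camera on MHC class II presentation gave adjusted p = 2.99e-06, or 0.301 with estimated correlation. H2-Ab1 and Cd74 changed by -3.32 ± 0.39 and -3.40 ± 0.66 (adjusted p from 0.000218 to 0.00258), and by -3.95 and -4.35 without P14 replicate 4. Of 9 genes of MHC class I presentation, 5 fell and 4 did not pass, and 5 fell when adjusted over the list alone. Camera on MHC class I presentation gave adjusted p = 0.0129, or 0.407 with estimated correlation. H2-K1 fell from 485 ± 89.0 to 142 ± 37.9 CPM and H2-D1 from 735 ± 84.8 to 249 ± 35.4 CPM (adjusted p from 0.0003 to 0.000774).

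Metabolic, complement and adventitial lists were lower by camera. Of 14 genes of cholesterol synthesis, 13 fell and 1 did not pass, and 13 fell when adjusted over the list alone. Camera on cholesterol synthesis gave adjusted p = 6.6e-08, or 0.369 with estimated correlation. Stard4, a cholesterol carrier, and Fdft1, the squalene synthase, changed by -1.86 ± 0.27 and -1.74 ± 0.26 (adjusted p from 0.000705 to 0.000708). Of 10 markers of CD81/PI16-type fibroblasts, which lie deep in the wall and around vessels, 1 rose, 5 fell and 4 did not pass, and 1 rose and 5 fell when adjusted over the list alone. Camera on CD81/PI16-type fibroblast markers gave adjusted p = 0.00654, or 0.407 with estimated correlation. Pi16 fell from 182 ± 17.7 to 23.1 ± 7.45 CPM and Ackr4, a scavenging chemokine receptor, from 167 ± 99.2 to 21.7 ± 10.1 CPM (adjusted p from 0.00134 to 0.00162). Of 9 complement genes, 4 fell and 5 did not pass, and 4 fell when adjusted over the list alone. Camera on complement gave adjusted p = 0.0105, or 0.452 with estimated correlation. C3, the central component, fell from 963 ± 225 to 41.8 ± 4.06 CPM (adjusted p = 0.000346). Of 16 genes of hypoxia and glycolysis, 5 fell and 11 did not pass, and 5 fell when adjusted over the list alone. Camera on hypoxia and glycolysis gave adjusted p = 0.0231, or 0.407 with estimated correlation. Hk2, a hexokinase, and the glucose transporter Slc2a1 changed by -1.39 ± 0.31 and -1.17 ± 0.28 (adjusted p from 0.00523 to 0.00711). Marker sums of 12 of 20 cell types passed the exact test at adjusted p = 0.0476, 3 higher and 9 lower in P14, all at the smallest p it allows. With mean log2(CPM + 1) in place of the log2 sum, 11 reached that p and 0 passed (adjusted p = 0.0519). That of 11 pan-fibroblast markers was lower, at 21830.0 ± 4355 against 14160.0 ± 2216 CPM, although the median log2 fold change of its members was 0.25. With the epithelial marker sum as a covariate, an alternative added after seeing the data, the count of changed genes fell from 5789 to 38, the median SE rose 2.07 times and Mcam stood at 1.89 with adjusted p = 0.0707.

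**Figure D3:**
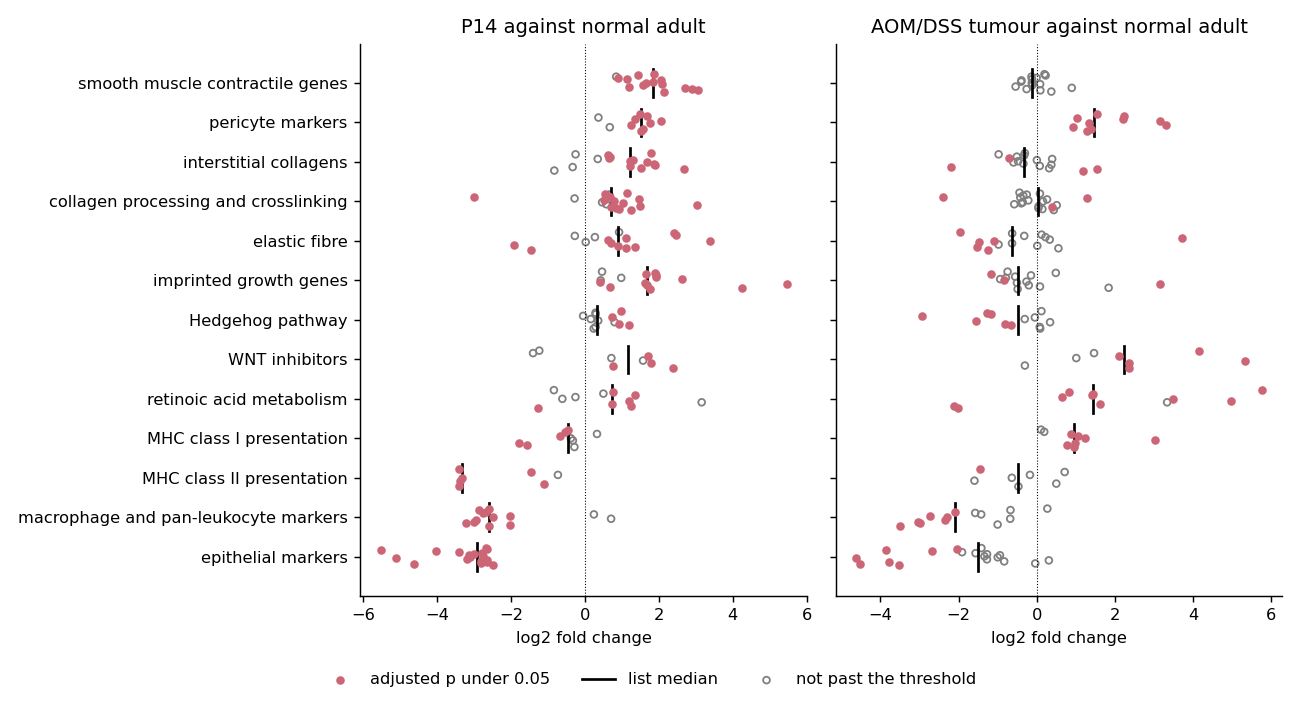
Log2 fold change (x axis) of each tested member (points, filled where adjusted p was under 0.05) of the gene lists named on the y axis, against normal adult for P14 and for tumour libraries, with the list median as a vertical bar. The pericyte list has medians of 1.51 and 1.47, and the smooth muscle list has medians of 1.84 in P14 and -0.12 in tumour libraries.

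The second comparison set stroma of AOM/DSS tumours against normal adult stroma. By camera, lists of pericyte genes, WNT inhibitors, matrix proteases, chemokines and retinoid-handling genes were higher in tumour libraries, and those of Hedgehog pathway genes and of epithelial, endothelial and macrophage markers lower. With estimated correlation 0 lists were called, and without tumour replicate 2 the protease and chemokine calls ended. Summed squamous epithelial genes, a list written after the data were seen, were higher too, at 7089 to 20520.0 CPM against 1538 CPM or less in other libraries. Notum, a secreted enzyme that inactivates WNT ligands, rose from 0.328 ± 0.151 to 13.2 ± 11.7 CPM (log2 fold change 5.33 ± 0.64, adjusted p = 0.000239), and Mmp13, a collagenase, from 4.21 ± 0.759 to 168 ± 154 CPM (log2 fold change 5.32 ± 0.72, adjusted p = 0.000489). Mcam rose from 65.3 ± 16.1 to 191 ± 23.6 CPM (fold 2.92, log2 fold change 1.55 ± 0.18, adjusted p = 0.000196). Hhip, a Hedgehog-binding protein induced by the pathway, fell from 185 ± 65.8 to 24.0 ± 8.32 CPM (log2 fold change -2.94 ± 0.36, adjusted p = 0.000274). The test called 3545 of 18727 genes, 1993 higher and 1552 lower in tumour libraries, and the values of 4128 tested genes (22.04%) did not overlap between the groups, against 2.86% by chance. Without normal adult replicate 3 the count was 2303. Without tumour replicate 3 the change of Notum was 4.53, and without tumour replicate 4 that of Mmp13 was 4.65.

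Of the 10 study genes, 2 rose, 4 fell and 4 did not pass, and 3 rose and 5 fell when adjusted over the list alone, with the same reservation on how they were chosen. Lepr, the leptin receptor, fell from 305 ± 116 to 42.1 ± 24.6 CPM, Islr from 116 ± 15.2 to 39.6 ± 19.6 CPM and Gli1, the transcription factor at the end of the Hedgehog pathway, from 36.3 ± 10.4 to 12.3 ± 1.94 CPM (adjusted p from 0.000402 to 0.00369). Fap, a fibroblast protease, fell from 147 ± 30.6 to 35.4 ± 27.8 CPM (log2 fold change -2.05 ± 0.49, adjusted p = 0.0119), and by 2.69 on the log2 scale without tumour replicate 2. Pdgfrb rose from 147 ± 36.8 to 297 ± 71.7 CPM (log2 fold change 1.02 ± 0.25, adjusted p = 0.0147), a call that ended without normal adult replicate 3 (adjusted p = 0.0508). The changes of the rest were 0.76 ± 0.33 for Grem1, 0.37 ± 0.25 for Acta2, -0.24 ± 0.26 for Pdgfra and -0.94 ± 0.37 for Postn, with adjusted p from 0.0984 to 0.563.

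By the same rule, the 8 largest rises in tumours included keratins and serine proteases. Krt13, a keratin of squamous mucosa, rose from 1.25 ± 0.613 to 533 ± 500.0 CPM and Krt6b, a keratin of activated squamous cells, from 0.153 ± 0.14 to 54.7 ± 49.3 CPM (adjusted p from 0.000107 to 0.000202). Ltf, the iron-binding protein lactotransferrin (ENSMUSG00000032496, chromosome 9, 111019271 to 111042767 on the plus strand), rose from 0.302 ± 0.172 to 542 ± 639.5 CPM and S100a9, a calprotectin subunit of neutrophils and squamous cells, from 0.334 ± 0.322 to 153 ± 253 CPM (adjusted p from 0.000529 to 0.00117). Calcb, a calcitonin gene-related peptide, rose from 0.593 ± 0.214 to 185 ± 149 CPM (log2 fold change 8.28 ± 0.68, adjusted p = 2.04e-05). Of the squamous serine proteases, Tmprss11b and Tmprss11d changed by 8.54 ± 1.05 and 9.51 ± 1.11, and Tmprss11g, with 2 counts in all normal adult libraries, was 2050-fold higher by pooled counts (95% counting interval 569 to 17000), with 2327 of its 3205 tumour counts in tumour replicate 3. Without tumour replicate 3 the log2 fold changes were 9.82 for Ltf, 7.60 for Calcb, 7.69 for Krt6b, 7.54 for Tmprss11b and 8.50 for Tmprss11d. Without tumour replicate 2 that of S100a9 was 6.31, without normal adult replicate 2 it was 9.61, and without normal adult replicate 4 that of Tmprss11b was 9.43, while Tmprss11d had 3 counts left. Keratin 6 and Tmprss11 genes have close copies and are uncertain.

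Among the 8 largest falls in tumours, Slc30a10, a manganese exporter, changed by -6.01 ± 0.83, H2-T3, a nonclassical MHC gene of gut epithelium, by -5.55 ± 0.86 and Btnl1, a butyrophilin-like gene of gut epithelium, by -4.52 ± 0.72. The others were -5.38 ± 1.22 for Ugt2b5, -4.85 ± 0.99 for Cyp2c65, -4.71 ± 1.25 for Cyp2c55, -4.62 ± 0.89 for Fabp2 and -4.53 ± 0.98 for Car1, with adjusted p from 0.00053 to 0.0204 over the 8. Without tumour replicate 4 they were -6.66 for Slc30a10, -6.54 for H2-T3, -6.45 for Cyp2c65, -7.19 for Cyp2c55, -6.59 for Fabp2 and -5.74 for Car1, while Ugt2b5 had 0 counts in the other 3 tumour libraries. The Cyp2c genes have close copies and are uncertain. Of 18 epithelial markers, 7 fell and 11 did not pass, and 11 fell when adjusted over the list alone. Camera on epithelial markers gave adjusted p = 2.95e-06, or 0.517 with estimated correlation. Cdx2, the transcription factor of intestinal epithelium, fell from 23.0 ± 7.28 to 1.67 ± 0.958 CPM (adjusted p = 0.00149), while the summed CPM of the list was 3926 ± 1757 in tumour against 11050.0 ± 4168 in normal adult libraries.

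Pericyte, WNT inhibitor and WNT target lists were higher in tumours by camera. Of 10 pericyte markers, 10 rose, and 10 rose when adjusted over the list alone. Camera on pericyte markers gave adjusted p = 1.58e-10, or 0.189 with estimated correlation. Higd1b, a pericyte gene, rose from 1.36 ± 0.445 to 13.4 ± 5.69 CPM, Rgs5 from 357 ± 84.7 to 1681 ± 647 CPM and the receptor Notch3 from 51.4 ± 18.4 to 236 ± 119.7 CPM (adjusted p from 0.000175 to 0.00229). Their summed CPM was 769.9 ± 192 in normal adult and 2718 ± 921 in tumour libraries. Of 15 smooth muscle contractile genes, 15 did not pass, and 0 passed when adjusted over the list alone (adjusted p = 0.925 by camera). At an unadjusted p under 0.05, edgeR had 1 higher and 0 lower. Myh11 was at 789 ± 206 and 725 ± 293 CPM. Of 8 WNT inhibitors, 5 rose and 3 did not pass, and 6 rose when adjusted over the list alone. Camera on WNT inhibitors gave adjusted p = 1.59e-05, or 0.109 with estimated correlation. Wif1 changed by 4.14 ± 0.51, Frzb by 2.36 ± 0.32 and Dkk2 by 2.34 ± 0.35 (adjusted p from 0.00029 to 0.000914), and Notum, the largest, as given above. Of 10 WNT/beta-catenin targets, 6 rose and 4 did not pass, and 8 rose when adjusted over the list alone. Camera on WNT/beta-catenin targets gave adjusted p = 0.00136, or 0.514 with estimated correlation. Apcdd1, an inhibitor that the pathway induces, rose from 19.3 ± 1.91 to 76.5 ± 44.1 CPM and Nkd1, another, from 9.63 ± 2.35 to 50.5 ± 51.5 CPM (adjusted p from 0.000894 to 0.013), with Nkd1 at 1.44 in place of 2.39 log2 units without tumour replicate 3. Of 11 genes of retinoic acid metabolism, 8 rose, 2 fell and 1 did not pass, and 9 rose and 2 fell when adjusted over the list alone. Camera on retinoic acid metabolism gave adjusted p = 1.7e-05, or 0.0668 with estimated correlation. Stra6, a retinol transporter, rose from 0.873 ± 0.369 to 47.3 ± 24.8 CPM and Crabp2, a retinoic acid carrier, from 0.514 ± 0.23 to 16.2 ± 7.88 CPM, whereas Aldh1a2, which makes retinoic acid, fell from 25.4 ± 3.88 to 5.75 ± 2.92 CPM (adjusted p from 2.78e-05 to 0.000532). Of 26 proliferation genes, 11 rose and 15 did not pass, and 12 rose when adjusted over the list alone. Camera on proliferation gave adjusted p = 8.59e-07, or 0.517 with estimated correlation. Rrm2 and Mcm2 changed by 1.62 ± 0.31 and 1.20 ± 0.24 (adjusted p from 0.00355 to 0.00514).

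Protease, cytokine and MHC class I lists were higher by camera. Of 20 matrix proteases and inhibitors, 6 rose, 1 fell and 13 did not pass, and 6 rose and 1 fell when adjusted over the list alone. Camera on matrix proteases and inhibitors gave adjusted p = 0.0113, or 0.517 with estimated correlation. Mmp10, Mmp3 and Mmp9 changed by 5.20 ± 0.75, 3.35 ± 0.60 and 4.06 ± 0.42 (adjusted p from 0.000105 to 0.00236), with Mmp10 at 4.47 without tumour replicate 4. Of 16 inflammatory chemokines and cytokines, 7 rose and 9 did not pass, and 8 rose and 1 fell when adjusted over the list alone. Camera on inflammatory chemokines and cytokines gave adjusted p = 0.00224, or 0.517 with estimated correlation. Cxcl5, a neutrophil attractant, rose from 3.37 ± 1.97 to 120.0 ± 71.9 CPM and Il11, a cytokine of activated fibroblasts, from 1.82 ± 0.504 to 33.2 ± 21.9 CPM (adjusted p from 0.000133 to 0.000725). Of 14 cancer-associated fibroblast markers, 7 rose, 1 fell and 6 did not pass, and 7 rose and 2 fell when adjusted over the list alone. Camera on cancer-associated fibroblast markers gave adjusted p = 0.0109, or 0.481 with estimated correlation. Besides Il11, Inhba, an activin subunit, rose from 4.80 ± 1.00 to 26.8 ± 14.7 CPM and Lrrc15 from 1.56 ± 0.812 to 9.05 ± 6.86 CPM (adjusted p from 0.00112 to 0.0155). Without tumour replicate 2 the camera calls of these 3 lists ended, with adjusted p = 0.107 for proteases, 0.102 for chemokines and 0.0734 for fibroblast markers. Of 13 TGF-beta ligands and targets, 3 rose and 10 did not pass, and 3 rose and 1 fell when adjusted over the list alone. Camera on TGF-beta ligands and targets gave adjusted p = 0.00615, or 0.481 with estimated correlation. Ltbp2, which binds latent TGF-beta, rose from 4.45 ± 0.437 to 58.8 ± 21.6 CPM (log2 fold change 3.72 ± 0.24, adjusted p = 1.03e-05), and the others were Il11 and Inhba. Of 9 genes of MHC class I presentation, 7 rose and 2 did not pass, and 7 rose when adjusted over the list alone. Camera on MHC class I presentation gave adjusted p = 0.000104, or 0.481 with estimated correlation. Nlrc5, the transactivator of these genes, rose from 6.99 ± 2.95 to 56.7 ± 11.3 CPM and H2-K1 from 485 ± 89.0 to 962 ± 199.7 CPM (adjusted p from 0.000928 to 0.0079). Of 5 neutrophil markers, 2 rose and 3 did not pass, and 3 rose when adjusted over the list alone (adjusted p = 0.0606 by camera). S100a8 changed by 8.14 ± 1.33 (adjusted p = 0.00145) and by 5.64 without tumour replicate 2.

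Hedgehog, endothelial and macrophage lists were lower by camera. Of 12 Hedgehog pathway genes, 6 fell and 6 did not pass, and 6 fell when adjusted over the list alone. Camera on Hedgehog pathway gave adjusted p = 0.006, or 0.517 with estimated correlation. The receptor Ptch1 fell from 202 ± 59.2 to 88.8 ± 15.8 CPM (adjusted p = 0.00675). Of 17 endothelial markers, 1 rose, 6 fell and 10 did not pass, and 2 rose and 14 fell when adjusted over the list alone. Camera on endothelial markers gave adjusted p = 0.000253, or 0.517 with estimated correlation. The receptor Tek fell from 138 ± 20.6 to 16.3 ± 9.88 CPM (adjusted p = 0.000274). Of 13 macrophage and pan-leukocyte markers, 7 fell and 6 did not pass, and 11 fell when adjusted over the list alone. Camera on macrophage and pan-leukocyte markers gave adjusted p = 2.94e-07, or 0.409 with estimated correlation. Adgre1, the macrophage antigen F4/80, and C1qa changed by -3.50 ± 0.59 and -3.00 ± 0.61 (adjusted p from 0.00171 to 0.00535), and by -4.23 and -3.72 without tumour replicate 2. Of 5 erythroid markers, 4 fell and 1 did not pass, and 5 fell when adjusted over the list alone. Camera on erythroid markers gave adjusted p = 0.000464, or 0.409 with estimated correlation. Hbb-bt, whose reads are shared with a close copy, changed by -3.68 ± 0.74 (adjusted p = 0.00507), or -4.53 without tumour replicate 1. Of 11 pan-fibroblast markers, 2 fell and 9 did not pass, and 2 fell when adjusted over the list alone. Camera on pan-fibroblast markers gave adjusted p = 0.0154, or 0.577 with estimated correlation. This call ended without normal adult replicate 1 (adjusted p = 0.0514) and without tumour replicate 3 (adjusted p = 0.114), and the decorin gene Dcn was at 3768 ± 713 and 2659 ± 1741 CPM (adjusted p = 0.41). Of 16 interstitial collagens, 2 rose, 2 fell and 12 did not pass, and 2 rose and 4 fell when adjusted over the list alone (adjusted p = 0.34 by camera). Col14a1, a collagen of fibril surfaces, fell from 1498 ± 291 to 328 ± 226 CPM (log2 fold change -2.19 ± 0.44, adjusted p = 0.00465). The exact permutation test on marker sums passed 0 of 20 lists after adjustment, although 8 reached p = 0.0286, the smallest it allows. Age and, by Xist, sex differ between these groups along with treatment: with sex as a covariate the count of changed genes was 2157, and in the libraries with Xist alone it was 644.

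**Figure D4:**
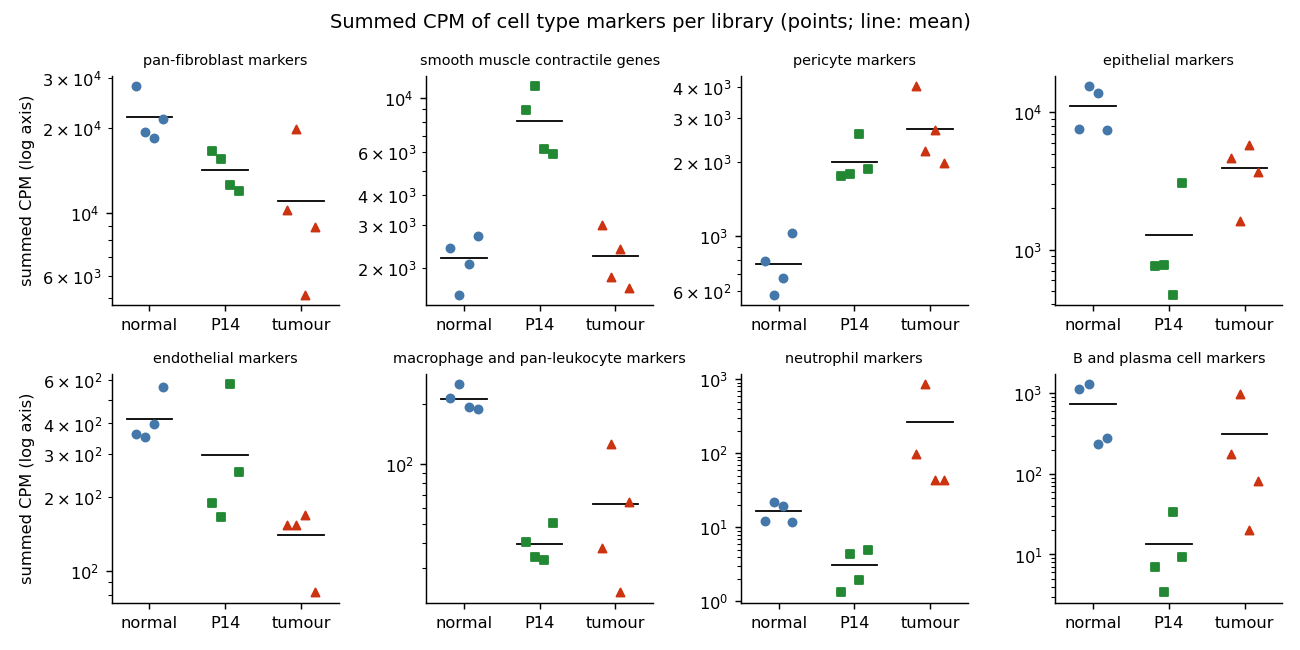
Summed CPM (y axis, log scale) of the markers of each named cell type in each library (points) by group (x axis), with the group mean as a line. Epithelial sums average 11050, 1271 and 3926 CPM and pericyte sums 770, 1995 and 2718 CPM in normal adult, P14 and tumour libraries.

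P14 and tumour stroma were set against the same normal adult libraries, which the series title links to where tumour stroma comes from. Genes changed in both went the same way more often than not: 532 were higher in both and 706 lower in both, and 325 went opposite ways. With the epithelial marker sum as a covariate, which overlaps with the groups, 24 were shared in the same direction and 1 in the opposite one. Epithelial sums were higher in every shared normal adult library than in any other, and several of the named falls are colonocyte genes. Serpina3f, a serine protease inhibitor (ENSMUSG00000066363, chromosome 12, 104214544 to 104221129 on the plus strand), changed by 4.03 ± 0.61 in P14 and 5.95 ± 0.63 in tumours, H19 by 5.46 ± 0.87 and 3.14 ± 0.80, and Bhlhe22, a transcription factor, by 2.61 ± 0.39 and 4.35 ± 0.41. The other named rises were 3.04 ± 0.61 and 4.26 ± 0.64 for Tex15, 2.71 ± 0.45 and 3.62 ± 0.47 for Serpina3g, 3.54 ± 0.44 and 2.54 ± 0.43 for Pimreg, 2.50 ± 0.45 and 4.47 ± 0.48 for Ntm and 2.44 ± 0.71 and 5.84 ± 0.80 for Cemip. Of the genes lower in both, Fabp2 (ENSMUSG00000023057, chromosome 3, 122895072 to 122899506 on the plus strand) fell from 210.3 ± 61.9 CPM to 6.01 ± 4.22 and 8.76 ± 13.2 CPM, and the sulfotransferase Sult1a1 from 132 ± 48.1 CPM to 7.92 ± 3.05 and 7.13 ± 2.54 CPM. The rest were -4.62 ± 1.24 and -4.71 ± 1.25 for Cyp2c55, -4.63 ± 0.98 and -4.53 ± 0.98 for Car1, -4.17 ± 0.75 and -4.21 ± 0.76 for Gal3st2c, -4.14 ± 0.69 and -4.52 ± 0.72 for Btnl1, -4.37 ± 0.50 and -3.94 ± 0.49 for Akr1c19 and -5.53 ± 0.82 and -3.86 ± 0.76 for Slc26a3. Adjusted p over these 16 genes ranged from 6.48e-05 to 0.0202 in P14 and from 2.85e-05 to 0.0204 in tumours. The call of Cemip in P14 ended without normal adult replicate 2 (adjusted p = 0.058), normal adult replicate 3 (0.0618) or P14 replicate 3 (0.0504). Without 1 library the tumour changes moved to 5.15 for Serpina3f and 2.99 for Serpina3g (tumour replicate 2), 3.35 for Tex15 and -4.87 for Gal3st2c (tumour replicate 3) and 2.48 for H19, 4.71 for Cemip, -7.19 for Cyp2c55, -6.59 for Fabp2 and -5.74 for Car1 (tumour replicate 4). Those in P14 moved to -5.73 for Fabp2, -5.39 for Cyp2c55, -5.56 for Car1, -4.84 for Gal3st2c, -5.27 for Btnl1 and -6.20 for Slc26a3 (P14 replicate 4).

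If the gene lists of both comparisons were independent, 546 genes would be shared in the same direction and 550.2 in opposite directions, against 1238 and 325 observed. In 20 simulations of unchanged groups that shared the normal adult libraries, 0 genes were called in both by edgeR, because at most 1 gene was called in either. Across genes, which are not independent replicates, the log2 fold changes correlated at r = 0.263, below the 0.503 of the simulations, while their covariance was 0.336 against 0.082, a difference of 0.254. The share with the same sign was 56.9%, against 66.6% in the simulations. With the normal adult libraries split 2 and 2 between the comparisons, the 6 ways gave 392 to 656 shared genes in the same direction, where independence gives 92.3 to 259, and 54 to 290.0 in opposite directions, where it gives 94.9 to 273. With normal adult replicates 2 and 3 as the controls of P14, the opposite count of 290.0 exceeded its 272.9, and 49.5% of genes had the same sign. The same-direction count was 784 without normal adult replicate 2 and 711 without normal adult replicate 3. The opposite count was 210.0, 168, 182, 213 and 207 without normal adult replicates 2, 3 and 4 and P14 replicates 1 and 2, and 508 without tumour replicate 2.

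**Figure D5:**
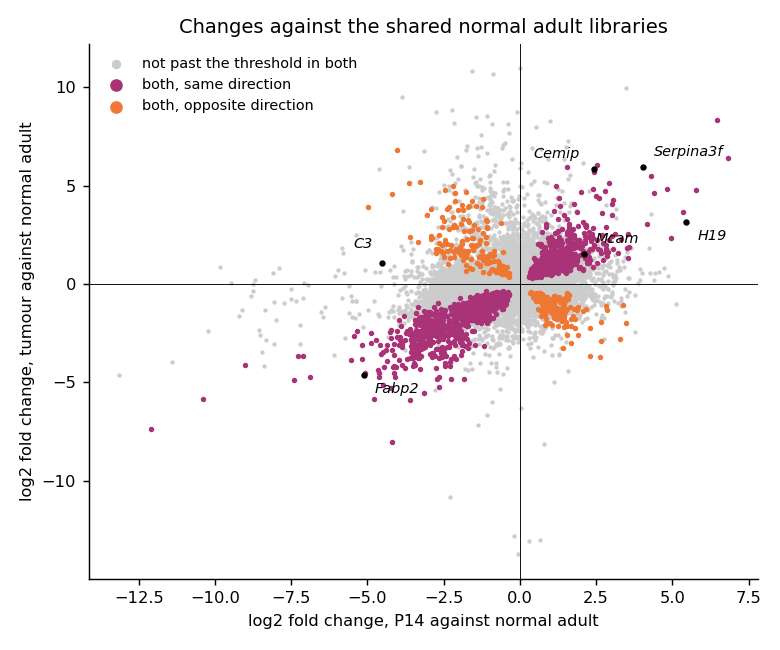
Log2 fold change of each tested gene in P14 (x axis) and in tumour libraries (y axis), both against the same normal adult libraries, with genes called in both coloured by whether they went the same or opposite ways. The 1238 genes with the same direction lie in the upper right and lower left, and the 325 with opposite directions in the upper left and lower right.

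The direct comparison of tumour with P14 stroma shares no libraries between its sides. By camera, lists of contractile, collagen, elastic fibre, imprinted and Hedgehog pathway genes were lower in tumour than in P14 stroma, and those of antigen-presentation, complement and cholesterol synthesis genes higher. With estimated correlation 0 of 20 lists were called. Col3a1, the fibrillar collagen of soft tissue, stood at 56751 ± 10192 CPM in P14 and 11647 ± 4638 CPM in tumours (log2 fold change -2.28 ± 0.30, adjusted p = 0.000167), and C3 at 41.8 ± 4.06 and 2044 ± 1802 CPM (log2 fold change 5.61 ± 0.61, adjusted p = 5.3e-05, and 4.89 without tumour replicate 2). The test called 6930 genes, 3696 higher and 3234 lower in tumours, and the values of 6027 tested genes (32.18%) did not overlap, against 2.86% by chance. Of the study genes, 1 rose and 7 fell, and 2 rose and 7 fell when adjusted over the list alone (adjusted p = 0.00121 by camera and adjusted p = 0.343 with estimated correlation), again a list chosen on the study's subject. The changes were -1.76 ± 0.26 for Acta2, -2.45 ± 0.39 for Postn, -2.48 ± 0.37 for Lepr, -1.92 ± 0.26 for Gli1 and -1.73 ± 0.30 for Islr (adjusted p from 0.000181 to 0.000901), and that of Fap was -2.62 ± 0.50 (adjusted p = 0.00162), or -3.27 without tumour replicate 2. Mcam changed by -0.57 ± 0.18 (adjusted p = 0.0238), a call that ended without P14 replicate 1 (adjusted p = 0.0621), P14 replicate 2 (0.0688) or tumour replicate 4 (0.0557). Grem1, a BMP antagonist, changed by 0.94 ± 0.33 (adjusted p = 0.0403) and lost its call without P14 replicate 1, 3 or 4 or tumour replicate 1 or 2, with adjusted p from 0.0585 to 0.116.

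The largest rises over P14 again included keratins and Tmprss11 proteases. Krt13 stood at 0.188 ± 0.173 and 533 ± 500.0 CPM, Krt6a at 0.325 ± 0.524 and 408 ± 204 CPM and S100a9 at 0.0658 ± 0.0473 and 153 ± 253 CPM in P14 and tumours (adjusted p from 3.73e-05 to 0.000298). Tmprss11d had 0 counts in P14 and was at least 2160-fold higher in tumours, against a floor of 3 counts over the group, and Tmprss11g had 1 count in P14 and a pooled ratio of 5060.0 (95% counting interval 909 to 200000). Tumour replicate 3 held 2662 of the 4095 tumour counts of Tmprss11d and 2327 of the 3205 of Tmprss11g, and the 1 P14 count was in P14 replicate 1. The others were 12.39 ± 1.62 for Ltf, 10.81 ± 0.71 for Tmprss11a and 9.91 ± 0.97 for Krt6b (adjusted p from 3.3e-06 to 0.00016). Col26a1 (ENSMUSG00000004415, chromosome 5, 136741759 to 136883209 on the minus strand) fell from 15.4 ± 1.67 to 0.181 ± 0.333 CPM and Vip, a neuropeptide, from 13.5 ± 6.58 to 0.202 ± 0.236 CPM. The remaining falls were -5.98 ± 0.48 for Plppr5, -5.46 ± 0.59 for Zim1, -5.11 ± 0.82 for Slc30a10, -4.48 ± 0.38 for Fbn2, -4.45 ± 0.39 for Cpz and -4.44 ± 0.86 for Col6a6, with adjusted p from 1.27e-05 to 0.00182 over the 8. Without 1 library the changes moved to 12.48 for Krt6a and 11.57 for Tmprss11a (P14 replicate 3), -4.32 for Slc30a10 and -3.67 for Col6a6 (P14 replicate 4), -5.14 for Col6a6 (tumour replicate 1), 8.51 for S100a9 (tumour replicate 2), 11.40 for Ltf, 9.12 for Krt6b and -6.70 for Vip (tumour replicate 3) and -5.76 for Slc30a10 (tumour replicate 4). Without P14 replicate 4, Ltf and Krt6b had 3 counts left in P14, and without tumour replicate 2 Col26a1 had 1 left in tumours.

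Contractile, collagen, elastic fibre, basement membrane and imprinted lists were lower in tumours than at P14 by camera. So were pan-fibroblast markers (adjusted p = 0.00655; 4 of 11 fell), matricellular proteins (0.00268; 7 of 12 fell and 1 rose), enteric glia markers (0.0188; 8 of 13 fell and 2 rose) and enteric neuron markers (0.0394; 7 of 11 fell and 2 rose). Without tumour replicate 2 the glia and neuron calls ended (adjusted p = 0.0721 and 0.133), and without P14 replicate 2 that of neurons (0.0775). Of 20 matrix proteases and inhibitors, 7 rose, 6 fell and 7 did not pass, and 7 rose and 6 fell when adjusted over the list alone (adjusted p = 0.897 by camera). Of 15 smooth muscle contractile genes, 15 fell, and 15 fell when adjusted over the list alone. Camera on smooth muscle contractile genes gave adjusted p = 4.79e-11, or 0.343 with estimated correlation. Cnn1 and Myocd, the smooth muscle coactivator, changed by -3.16 ± 0.35 and -2.24 ± 0.30 (adjusted p from 5.45e-05 to 0.000185), beside a marker sum of 8027 ± 2508 in P14 and 2224 ± 612 CPM in tumours. Of 16 interstitial collagens, 1 rose, 13 fell and 2 did not pass, and 1 rose and 13 fell when adjusted over the list alone. Camera on interstitial collagens gave adjusted p = 5.92e-08, or 0.272 with estimated correlation. Col1a2 and Col8a2 changed by -2.22 ± 0.20 and -2.10 ± 0.28, and Col10a1 by 2.02 ± 0.37 (adjusted p from 2e-05 to 0.00142). Of 19 genes of collagen processing and crosslinking, 1 rose, 15 fell and 3 did not pass, and 1 rose and 16 fell when adjusted over the list alone. Camera on collagen processing and crosslinking gave adjusted p = 4.73e-07, or 0.41 with estimated correlation. Lox and the collagen chaperone Serpinh1 changed by -2.52 ± 0.21 and -1.57 ± 0.20 (adjusted p from 1.27e-05 to 0.000135). Of 15 elastic fibre genes, 1 rose, 8 fell and 6 did not pass, and 2 rose and 8 fell when adjusted over the list alone. Camera on elastic fibre gave adjusted p = 0.000584, or 0.422 with estimated correlation. Mfap4 changed by -3.03 ± 0.37 and elastin, Eln, by -2.87 ± 0.43 (adjusted p from 0.000109 to 0.000381), or -3.62 without tumour replicate 2. Of 18 basement membrane genes, 3 rose, 10 fell and 5 did not pass, and 3 rose and 11 fell when adjusted over the list alone. Camera on basement membrane gave adjusted p = 0.00122, or 0.518 with estimated correlation. Col4a5 and Lama2 changed by -2.86 ± 0.35 and -1.48 ± 0.26 (adjusted p from 0.000105 to 0.00108). Of 15 imprinted growth genes, 14 fell and 1 did not pass, and 15 fell when adjusted over the list alone. Camera on imprinted growth genes gave adjusted p = 3.53e-09, or 0.106 with estimated correlation. Mest and Peg3 changed by -3.57 ± 0.40 and -2.83 ± 0.23 (adjusted p from 1.27e-05 to 6.07e-05). Of 12 Hedgehog pathway genes, 8 fell and 4 did not pass, and 8 fell when adjusted over the list alone. Camera on Hedgehog pathway gave adjusted p = 8.23e-06, or 0.343 with estimated correlation. Foxf1 changed by -1.84 ± 0.20 and Foxf2 by -1.74 ± 0.22 (adjusted p from 4.44e-05 to 0.000131). Of 13 BMP ligands and targets, 5 fell and 8 did not pass, and 1 rose and 5 fell when adjusted over the list alone. Camera on BMP ligands and targets gave adjusted p = 0.00165, or 0.343 with estimated correlation. Id4, a target of BMP signals, and Bmp4 changed by -1.82 ± 0.19 and -1.45 ± 0.20 (adjusted p from 3.65e-05 to 0.000253).

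Camera called MHC, complement, neutrophil and metabolic lists higher in tumours than at P14, but not inflammatory chemokines (adjusted p = 0.121) or interferon response (0.363). Of 13 macrophage and pan-leukocyte markers, 2 rose, 2 fell and 9 did not pass, and 1 rose and 2 fell when adjusted over the list alone (adjusted p = 0.897 by camera). Of 9 genes of MHC class I presentation, 9 rose, and 9 rose when adjusted over the list alone. Camera on MHC class I presentation gave adjusted p = 1.77e-07, or 0.272 with estimated correlation. H2-K1 and H2-D1 changed by 2.76 ± 0.23 and 2.32 ± 0.24 (adjusted p from 1.27e-05 to 3.73e-05). Of 7 genes of MHC class II presentation, 6 rose and 1 did not pass, and 6 rose when adjusted over the list alone. Camera on MHC class II presentation gave adjusted p = 0.000584, or 0.343 with estimated correlation. H2-DMb1 changed by 2.17 ± 0.28 (adjusted p = 0.000147). Of 9 complement genes, 6 rose and 3 did not pass, and 6 rose when adjusted over the list alone. Camera on complement gave adjusted p = 0.00102, or 0.518 with estimated correlation. C4b changed by 4.24 ± 0.50 (adjusted p = 8.78e-05), or 3.62 without tumour replicate 2. Of 14 genes of cholesterol synthesis, 12 rose and 2 did not pass, and 13 rose when adjusted over the list alone. Camera on cholesterol synthesis gave adjusted p = 6.37e-06, or 0.423 with estimated correlation. Lss and Fdft1 changed by 1.43 ± 0.20 and 1.65 ± 0.26 (adjusted p from 0.000212 to 0.000459). Of 16 genes of hypoxia and glycolysis, 12 rose and 4 did not pass, and 13 rose when adjusted over the list alone. Camera on hypoxia and glycolysis gave adjusted p = 0.000304, or 0.343 with estimated correlation. Slc2a1 and Eno1, the enolase, changed by 1.79 ± 0.28 and 1.59 ± 0.22 (adjusted p from 0.000204 to 0.000486). Of 5 neutrophil markers, 5 rose, and 5 rose when adjusted over the list alone. Camera on neutrophil markers gave adjusted p = 0.00632, or 0.343 with estimated correlation. Without tumour replicate 2, the change of Csf3r was 2.91 in place of 5.32 ± 1.18, and without P14 replicate 4 it had 3 counts left in P14. Of 18 epithelial markers, 7 rose and 11 did not pass, and 9 rose when adjusted over the list alone. Camera on epithelial markers gave adjusted p = 0.0131, or 0.741 with estimated correlation. This call ended without tumour replicate 3 (adjusted p = 0.0521). Of 10 pericyte markers, 2 rose and 8 did not pass, and 2 rose when adjusted over the list alone (adjusted p = 0.372 by camera). Higd1b changed by 2.05 ± 0.35 (adjusted p = 0.000927), and the pericyte sums were 1995 ± 392 and 2718 ± 921 CPM. Marker sums passed the exact permutation test for 0 of 20 lists after adjustment, with 4 at the smallest p of 0.0286, or 7 lists without overlap when P14 replicate 3 or tumour replicate 3 was left out. With the epithelial sum as a covariate the count of changed genes was 2517.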

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

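Among 99 groups of 4 libraries, 4 held a library far from the other 3 by a gap test at a 95% level, where chance gives 1 in 20, or 4.95. No test here was chosen after the result was seen, and no explanation was tested for any of the 4. The summed markers of interstitial cells of Cajal were 377 CPM in normal adult replicate 1 against 479 to 491 CPM in the other normal adult libraries. The summed pericyte markers were 2578 CPM in P14 replicate 3 against 1752 to 1864 CPM in the other P14 libraries. In tumour replicate 4, the library with the lowest total count, 9.14% of listed genes were at 0 against 0.782% to 0.850% in the other tumour libraries. The same library had 81.6 CPM of summed endothelial markers against 154 to 169.5 CPM.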

How the results depend on the processing

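The values with the epithelial marker sum or sex as a covariate and with the libraries with Xist alone, the count at P14 without tumour replicate 4 (6704) and the counts of cell type lists without overlap were chosen after the data were seen. The others were planned. Of the described genes called in each comparison, 4 of 143 at P14, 45 of 113 in tumours and 75 of 103 in tumours against P14 kept their call under every alternative. In 2 of these comparisons, tumour against normal adult and tumour against P14, no described gene reversed. Most losses at P14 came from the epithelial covariate, under which 130 of 143 called genes lost their call and 5 reversed, and from the libraries with Xist alone, where 137 did. Of the sum's variance, 82.5% lies between these groups, so the covariate and the group overlap. Under DESeq2's own test, 1 described gene at P14 lost its call. No scaling moved the share of higher calls by over 10 points or the median of all genes by over 0.1. Most 2-fold changes were missed in simulation, where far fewer genes were changed than were called in the data.

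Leaving out 1 of the 8 compared libraries gave 4149 to 5393 changed genes at P14 (5789 with all, and 6704 without tumour replicate 4), 2303 to 4168 in tumours (3545) and 5363 to 7601 in tumours against P14 (6930). In the overlap of P14 and tumour changes, same direction, leaving out 1 of 12 gave 711 to 1406 genes (1238). In the overlap of P14 and tumour changes, opposite direction, it gave 168 to 508 (325). There were 28 to 31, 15 to 22 and 20 to 23 lists called by camera and 12 to 15, 8 to 10 and 4 to 7 cell type lists without overlap. In the same order of comparisons, an adjusted p under 0.01 gave 3135, 1550.0 and 4044 genes and 451 shared in the same and 85 in opposite directions, and a 2-fold minimum gave 3559, 2281 and 4221 genes and 761 and 183 shared, since both are stricter. With the title number as a replicate block the counts were 2953, 818 and 3740.0 genes, 280.0 and 76 shared, and 25 lists in tumours. Whether the numbers pair the libraries is not settled. Same-number correlations ran from -0.292 to 0.319, and 3 of 9 libraries with a shared number were closest to their own number. limma voom gave 11580 genes at P14 and 644 opposite genes, and DESeq2 gave 581 opposite genes. The epithelial covariate gave 38 genes at P14 and 2517 in tumours against P14, with 24 shared in the same and 1 in the opposite direction. Sex as a covariate gave 2157 genes in tumours and 167 opposite genes. The libraries with Xist alone gave 23, 644 and 1999 genes and 6 and 1 shared, within the ranges of 0 to 3131, 524 to 1517 and 1665 to 4508 over all 36 choices of 2 libraries per halved group. Split normal adult libraries gave 439, 473, 409, 392, 656 and 496 genes in the same and 110.0, 93, 54, 99, 68 and 290.0 in opposite directions, with fewer samples per comparison. An estimated correlation gave 2, 0 and 0 lists by camera, with 6, 6 and 6 at an unadjusted p under 0.05 and 35, 23 and 28 by fry, and fry's mixed test gave 48, 41 and 47. Mean log2(CPM + 1) in place of the log2 sum gave 0 cell type lists at P14 by the exact test, against 12. The first principal component of all tested genes held 39.7%.

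Reversals came with the epithelial covariate alone. At P14 they were pan-fibroblast markers (adjusted p = 0.0146 by camera), epithelial markers (0.646), matrix proteases (0.772), BMP antagonists (0.98), interferon response (0.0398), hypoxia (0.753) and mitochondrially encoded genes (0.00361), and in tumours against P14 epithelial markers (0.171). At P14 the log2 fold changes of Dhcr7, Dkk3, Erbb3, Fstl1 and Plk1 became 0.11, -0.030, 0.62, -0.28 and 0.23. Except where the stricter threshold, fewer samples or the overlap of covariate and group explains a value by construction, the cause was not tested.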

Other observations

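Of the tests of explanations in this part, those on pericyte medians, colonic epithelial markers, Xist and Y-linked counts, sex and other splits of the libraries were chosen after the results were seen. Some patterning, glia and clock genes rose and others fell. At P14, of 11 posterior HOX genes, 2 rose, 1 fell and 8 did not pass, and 2 rose and 1 fell when adjusted over the list alone (adjusted p = 0.605 by camera). The list's median was 0.25 and its mean -0.14. Hoxb13, the HOX gene of the hindmost gut, fell from 80.6 ± 41.1 to 10.3 ± 8.31 CPM (log2 fold change -2.97 ± 0.51, adjusted p = 0.0015), or by 3.70 on the log2 scale without P14 replicate 4, and stood at 40.8 ± 11.2 CPM in tumours. In tumours against P14, of 11 posterior HOX genes, 2 rose, 5 fell and 4 did not pass, and 2 rose and 5 fell when adjusted over the list alone (adjusted p = 0.278 by camera and adjusted p = 0.703 with estimated correlation), with Hoxd9 and Hoxa11 at -1.67 ± 0.30 and -1.28 ± 0.27. Of 13 enteric glia markers at P14, 6 rose, 2 fell and 5 did not pass, and 6 rose and 2 fell when adjusted over the list alone. Camera on enteric glia markers gave adjusted p = 0.0257, or 0.407 with estimated correlation. Fabp7, a lipid carrier of glia, rose from 1.73 ± 0.586 to 19.9 ± 12.7 CPM (adjusted p = 0.000772), and the call of the list ended without normal adult replicate 2 (adjusted p = 0.0537) or tumour replicate 2 (0.0655). In tumours, of 13 enteric glia markers, 2 rose, 3 fell and 8 did not pass, and 2 rose and 5 fell when adjusted over the list alone (adjusted p = 0.419 by camera and adjusted p = 0.754 with estimated correlation): Sox2, a transcription factor of glia that squamous epithelium also uses, rose from 0.679 ± 0.373 to 17.3 ± 4.25 CPM and the potassium channel Kcna1 fell from 12.4 ± 6.97 to 3.13 ± 1.56 CPM (adjusted p from 4.59e-05 to 0.00601). Of 12 circadian clock genes at P14, 4 rose, 3 fell and 5 did not pass, and 5 rose and 3 fell when adjusted over the list alone (adjusted p = 0.789 by camera). Npas2 and Nr1d1 changed by -2.13 ± 0.41 and -1.83 ± 0.36 (adjusted p from 0.00258 to 0.00295). In tumours 0 of 12 clock genes passed edgeR's test, and 0 when adjusted over the list alone, with 1 higher and 1 lower at an unadjusted p under 0.05. Camera gave adjusted p = 0.896 with a lower direction, although the median of the list was 0.16.

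Some WNT, lymphoid-tissue and interferon genes changed in tumours, but camera called none of these lists. Of 11 WNT ligands and R-spondins, 2 rose, 3 fell and 6 did not pass, and 2 rose and 3 fell when adjusted over the list alone (adjusted p = 0.419 by camera). Wnt2 fell from 20.3 ± 5.99 to 4.05 ± 1.80 CPM, while Wnt4 rose from 16.9 ± 5.24 to 44.2 ± 16.1 CPM and Wnt6 from 2.46 ± 0.284 to 8.90 ± 7.29 CPM (adjusted p from 0.000809 to 0.0157), with Wnt6 at 1.14 in place of 1.86 log2 units without tumour replicate 3. Of 8 lymphoid-tissue stroma markers, 3 rose and 5 did not pass, and 5 rose and 1 fell when adjusted over the list alone (adjusted p = 0.226 by camera). Cxcl13, the chemokine of B cell follicles, rose from 3.25 ± 1.67 to 32.9 ± 34.2 CPM and Tnfsf11, the ligand RANKL, from 0.479 ± 0.072 to 4.73 ± 5.35 CPM (adjusted p from 0.00407 to 0.0133), with log2 fold changes of 3.34 and 3.30 that became 2.53 and 2.11 without tumour replicate 2. Of 15 interferon response genes, 5 rose and 10 did not pass, and 6 rose and 1 fell when adjusted over the list alone (adjusted p = 0.0606 by camera). Cxcl9 rose from 0.553 ± 0.299 to 9.41 ± 5.86 CPM and Cxcl10 from 8.27 ± 1.74 to 22.1 ± 6.17 CPM (adjusted p from 0.00193 to 0.00836).

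Epithelial markers were lower than normal in both other groups although the sort removed EPCAM-positive cells. A second list held 25 epithelial junction and regulator genes, none in another list and all over 1 CPM in normal adult libraries. It was 100% lower at P14, which fits more epithelial cells in the normal adult sorts. In tumours 4% of it was lower, with a median log2 fold change of -0.45, which argues against fewer epithelial cells of every kind. A lower share of fibroblasts in the normal adult sorts would have raised every other cell type there. Pericyte medians of 1.51 at P14 and 1.47 in tumours cannot decide this, since pericytes may have risen. A change in the epithelial cells themselves with age stays open and untested at P14, and in tumours a change in the kind of epithelium may remain, since squamous cells share junction genes.

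Squamous keratins were high in tumour libraries of a colonic sort. A squamous list of 25 genes, none in another list, was also written after the data were seen. Among its 22 tested members, 90.91% were higher in tumours (median 3.82). This fits squamous epithelial cells in the sorted fraction. How far the EPCAM gate removes such cells was not tested. The list's most abundant tumour genes were Krt14, at 1936 to 8927 CPM, and Krt5, at 1341 ± 534 CPM. In normal adult libraries 21 members averaged over 1 CPM and Krt5 45.0 ± 29.7 CPM. Krt14 was at 4.77 CPM in normal adult replicate 1 and 139 to 187 CPM in the others. A single odd library is excluded, since all 4 tumour sums, 7089 to 20520.0 CPM, exceeded all others, at 1538 CPM or less. More colonic epithelium is also argued against, since 0 of 18 epithelial markers were higher by edgeR (0 higher and 13 lower at an unadjusted p under 0.05). Whether such cells came from the tumours or from nearby anorectal tissue was not tested.

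All 4 tumour libraries had at most 1 Y-linked count although 2 males were stated. Loss of the Y chromosome in male cells would leave Xist off, but the lowest tumour value was 481.4 CPM. A swap with another group would leave a surplus there, but the highest number of libraries without Xist in another group was 2, as stated. Animals of another sex than stated fit, with 4 of 4 libraries above 100 CPM of Xist and with at most 1 Y-linked count. Sex as a covariate, if its effect is the same in every group, gave 2157 and 4880 changed genes in tumours against normal adult and P14, and the libraries with Xist alone gave 644 and 1999. A swap with samples outside the series was not tested.

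Higher Mcam may follow from more pericytes. At P14 the log2 ratio of Mcam to summed pericyte markers was 0.754 above normal adult (SD 0.38 and 0.167, higher in 4 of 4 libraries, exact permutation p = 0.0286, adjusted p = 0.0572). Pericytes alone may not explain it, but the adjusted p misses 0.05. Smooth muscle sums also rose (2182 to 8027 CPM), a cause not tested. In tumours the ratio differed by -0.225 (SD 0.308, exact permutation p = 0.286), which fits pericyte content. Other splits of the 8 libraries, 35 per comparison, mix the groups. Only the real split gave as many changed genes: 5789 against 3 at most at P14 and 3545 against 2 in tumours. In tumours against P14 it was 6930 against 762. Mixing turns group difference into spread, so this cannot decide on chance. As many lists as the real 29, 16 and 20 were called by camera in 2, 15 and 16 splits. The others reached 29, 24 and 28, so chance is not excluded for those counts.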
